A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

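Strand-specific total RNA, depleted of ribosomal RNA, was sequenced from 8 libraries of Saccharomyces cerevisiae BY4741. There were 2 biological replicates each of WT with DMSO, WT with anisomycin (ANS), upf1 with DMSO and upf1 with ANS. Per the labels, reads were processed with Trim Galore, HISAT2 2.2.0, featureCounts 2.0.0 and DESeq2 on build R64, and the role of each tool in the deposited values is not stated. The deposited values are normalized densities (signal), for 11966 features and 8 libraries, with 4 further columns that hold the authors' group means of the same signal. All group means equalled the mean of the 2 replicates, with a tolerance of 1e-06 of the value. For 100% of the features with a value above 0, 1 length between 20 and 20000 nt turned the 8 densities into whole reads times 1 factor per library, with a tolerance of 1e-05 reads. None of 2000 features with randomly moved values got such a length. The factors equalled inverse median-ratio size factors of the 76 snoRNAs read in every library, up to a ratio of 1.01. The deposited densities are therefore taken as reads per nt scaled on snoRNAs, although the authors' scaling basis is not stated. Reads recovered this way depend on the length found and are used for depth, not for the tests. Per library they numbered 6954353 to 11994371. Of the features, 1311 had a library maximum under 10 reads and 12 were listed at 0 in all libraries. Spike-in RNA named in the protocol was not used here.

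Features were assigned to classes by their names and, for 6120 of them, by a match to the R64 gene table. Of 5858 protein-coding features with a length, 5076 were longer than the annotated coding length and 740 equal to it. Coordinates of XUTs, CUTs, SUTs and NUTs were not used here. These classes overlap in part with each other and with genes, and whether reads in overlaps were counted more than once is not given, nor is the treatment of reads that match several places.

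Tests used limma 3.58.1 in R 4.3.3 on log2(density + 0.003397), the pseudocount being the 5th percentile of values above 0. Features with a mean at or above it were tested, 11579 in all, with 387 left out. A model with 1 mean per group was fitted to all 8 libraries, with a variance trend and two-sided moderated tests (4 residual degrees of freedom, median 9.7 after moderation). Each of 5 comparisons was adjusted by Benjamini and Hochberg at 0.05. They were ANS against DMSO in WT and in upf1, upf1 against WT in DMSO and under ANS, and the interaction. The model, filter, pseudocount, comparisons, gene lists, rule for named genes and alternative settings were chosen before the data were examined. Classes of 10 or more features and lists of 4 or more were tested against other features with camera of limma at a preset correlation of 0.01, adjusted within a comparison, and again with an estimated correlation. The level of a class is its median density over that of protein-coding genes in each library. Its contrasts have 95% intervals from the spread within the 4 groups, and no pseudocount. This measure and the comparison of each class member with the 20 protein-coding genes nearest in mean density, which lay within 0.405 (log2) for XUTs, were added after the data were seen. Changes relative to protein-coding genes come from a fit to densities rescaled so that the median ratio of protein-coding genes to their geometric mean is 1, with the pseudocount in deposited units. Errors are the SE of the fit or the SD of 2 replicates. Whole-read values carry counting error only as far as reads are independent molecules.

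The genes named follow a rule. For ANS in WT and upf1 in DMSO these are the 6 protein-coding genes with the largest rise and the 6 with the largest fall past the threshold. Their mean density had to lie above the median of tested protein-coding genes, and the 2 libraries of one group had to lie beyond both of the other. By the same rule 5 XUTs that rose and up to 3 that fell, 3 CUTs and 3 SUTs were taken. The other comparisons gave the 4 largest rises and 4 largest falls over all features. From each list past the set test up to 3 members with the smallest adjusted p were named, and NAM7, NMD2, UPF3, EBS1, CPA1, ALR1 and the deleted marker genes always. Where such a feature had 1 to 3 reads or none in a group, densities or reads are given and no fold.

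Of 26 lists fixed from general knowledge, 25 were tested. They were NMD substrate mRNAs, mRNA decay and ribosome rescue factors, cytosolic ribosomal proteins, ribosome biogenesis, translation factors, the induced environmental stress response, heat shock factor targets and the proteasome. Metabolic lists were Gcn4 targets of amino acid synthesis, sulfur assimilation, glycolysis and fermentation, respiration, mitochondrially encoded genes, hexose transporters, ergosterol synthesis and nitrogen catabolite genes. The others were pleiotropic drug resistance, histones, G1 and S phase genes, G2, M and early G1 genes, the iron regulon, the phosphate regulon, a-cell, alpha-cell and meiosis genes. The deleted marker genes, which check the labels, are given as values, and 1 further gene of that list is not analysed here.

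The replicate numbers were checked for pairing. Correlations of the replicate differences between groups ranged from -0.16 to 0.22, and not all exceeded 0.1, so that replicates were treated as sharing only a number. Within groups the Pearson correlation of log2 values was 0.985 in WT DMSO, 0.977 in WT ANS, 0.987 in upf1 DMSO and 0.985 in upf1 ANS. The test was tried on simulated data with 9700 features, of which 67 were changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. It recovered 8.96% of 1.5-fold changes, 55.2% of 2-fold changes and 98.5% of 4-fold changes, and 8.47% of 118 calls were false. All 10 false calls had a mean under 10 reads. The changed features were drawn from well-read ones and the rest left unchanged, so that these rates do not carry over to ANS, under which most features moved. The settings fixed beforehand for comparison were 0.2 and 5 times the pseudocount, no filter, a filter at the 25th percentile, rescaling to protein-coding genes or to snoRNAs, limma without trend or with robust moderation, and only the 4 samples compared. A replicate block, a 2-fold minimum, an estimated correlation and leaving out each library were planned as well. Count tests with edgeR and DESeq2 were planned only for counts and were not run, because recovered reads depend on the lengths found. Limma-voom on the recovered reads, a minimum of 80 reads, the matched densities and the split of the WT DMSO libraries between both effects, with the spread of the other groups, were added after the data were seen.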

Results

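The series measured strand-specific total RNA, depleted of ribosomal RNA, in Saccharomyces cerevisiae BY4741, a haploid laboratory strain of mating type a, and in its upf1 mutant. Upf1, encoded by NAM7, is the RNA helicase at the core of nonsense-mediated decay (NMD), which destroys RNAs whose translation ends early. Cultures received anisomycin (ANS), which blocks peptide bond formation on the ribosome, at 100 µg/ml for 30 min, or its solvent DMSO. Each of the 4 groups, WT DMSO, WT ANS, upf1 DMSO and upf1 ANS, held 2 biological replicates. Besides genes, the deposited densities cover long noncoding RNAs that are usually degraded. XUTs are sensitive to the cytoplasmic exonuclease Xrn1, CUTs to the nuclear exosome and NUTs to the termination factor Nrd1, while SUTs are stable unannotated transcripts.

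Reads recovered from the densities numbered 6954353 and 9247260 in WT DMSO replicates 1 and 2, 7152322 and 8498946 in WT ANS, 9484034 and 10637051 in upf1 DMSO and 9637462 and 11994371 in upf1 ANS. The densities are on a scale that holds small nucleolar RNAs (snoRNAs) level, so that changes are given against snoRNAs unless stated otherwise. On that scale the median density of protein-coding genes was 0.144 and 0.145 in WT DMSO, 0.470 and 0.596 in WT ANS, 0.188 and 0.171 in upf1 DMSO and 0.565 and 0.507 in upf1 ANS. The share of reads on snoRNAs was 5.74 and 6.17% in WT DMSO, 3.28 and 2.69% in WT ANS, 5.92 and 6.20% in upf1 DMSO and 3.10 and 3.31% in upf1 ANS. Whether ANS changed the amount of mRNA per cell or that of snoRNAs is not given by these values. Changes relative to protein-coding genes, from libraries rescaled to their median ratio, are therefore given as well. The rescaling moved the median of protein-coding genes from 1.73 to 0.07 for ANS in WT, from 1.44 to -0.02 for ANS in upf1 and from 0.10 to -0.13 for upf1 in DMSO.

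The genotype labels were checked on NAM7 (YMR080C, R64 chromosome XIII, 426712 to 429627). Its density was 0.432 and 0.449 in WT DMSO and 0.0113 and 0.00975 in upf1 DMSO, so that the mutant held 2.39% of the WT level. Under ANS it was 1.24 and 1.59 in WT and 0.0210 and 0.0244 in upf1, or 1.60%. Of the genes deleted in BY4741, LEU2 had 0 to 2 reads and URA3 had 0 to 2 reads in each library. HIS3 (YOR202W), whose deletion allele keeps part of the gene, had a density of 0.223 ± 0.0225 (SD, n = 2) in WT DMSO. Strand separation was checked on 7 protein-coding genes that overlap another gene on the opposite strand. In 4 of them the density lay below 2% of the partner's, from 0.0581% for YDR209C opposite CPP2, and the median was 1.20%. The highest was 31.5%, for FYV5 opposite ADF1.

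ANS in WT cells addresses which RNAs accumulate when ribosomes stall. The largest rise among abundant protein-coding genes was that of CIT2 (YCR005C, R64 chromosome III, 120946 to 122328), the peroxisomal citrate synthase of the glyoxylate cycle, from 0.261 ± 0.0790 to 25.8 ± 4.57 (density, SD, n = 2), a log2 change of 6.63 ± 0.22 (SE) with adjusted p = 1.33e-07. The sporulation gene SPO24 (YPR036W-A) rose by 5.89 ± 0.19, the transcriptional repressor gene NRG1 (YDR043C) by 5.74 ± 0.16 and ARO10 (YDR380W), a decarboxylase of aromatic amino acid breakdown, by 5.35 ± 0.15. YHR022C rose by 4.98 ± 0.19 and the autophagy gene ATG41 (YPL250C) by 4.86 ± 0.21. Few features fell against snoRNAs. The abundant protein-coding genes among them included the hexokinase gene HXK1 (YFR053C, -0.97 ± 0.18, adjusted p = 5.09e-04), the Hsp70 genes SSA2 (YLL024C, -0.76 ± 0.15) and SSA1 (YAL005C, -0.70 ± 0.17), and the S-adenosylmethionine synthetase gene SAM1 (YLR180W, -0.70 ± 0.20). The glyceraldehyde-3-phosphate dehydrogenase gene TDH2 (YJR009C, -0.56 ± 0.16) and the transporter gene AQR1 (YNL065W, -0.55 ± 0.21, adjusted p = 0.0320) fell as well. SSA1 and SSA2, like TDH2 and its paralogs, are near identical, and how reads matching both were counted is not given.

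Of 11579 features tested, 10439 rose and 40 fell in WT under ANS, and 4069 rose and 2261 fell relative to protein-coding genes. Among protein-coding genes 5545 of 5777 rose, with a median of 1.73. The median rise was 2.11 for XUTs, 2.02 for SUTs, 1.77 for NUTs and 1.57 for CUTs. It was 0.61 for tRNAs, 0.33 for open reading frames of Ty elements, 0.15 for the 19 mitochondrially encoded protein-coding features and -0.08 for spliceosomal snRNAs. These fitted medians hold the pseudocount, which shrinks the changes of sparse classes. Median densities in WT DMSO were only 0.00443 for NUTs, 0.00651 for XUTs and 0.00728 for CUTs. Without a pseudocount, levels relative to the protein-coding median rose by 0.76 for XUTs, 0.68 for NUTs and 0.57 for SUTs (log2). For CUTs the difference was 0.15 (95% interval -0.24 to 0.55). The fitted medians therefore do not rank NUTs and CUTs against protein-coding genes. The rise was smaller for abundant mRNAs, with a median of 1.99 in bin 3 and 0.85 in bin 10 of protein-coding genes in 10 bins by rising density. The count of falls rose to 103 without WT ANS replicate 2, in which the median protein-coding density lay 0.33 (log2) above that of replicate 1.

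**Figure D1:**
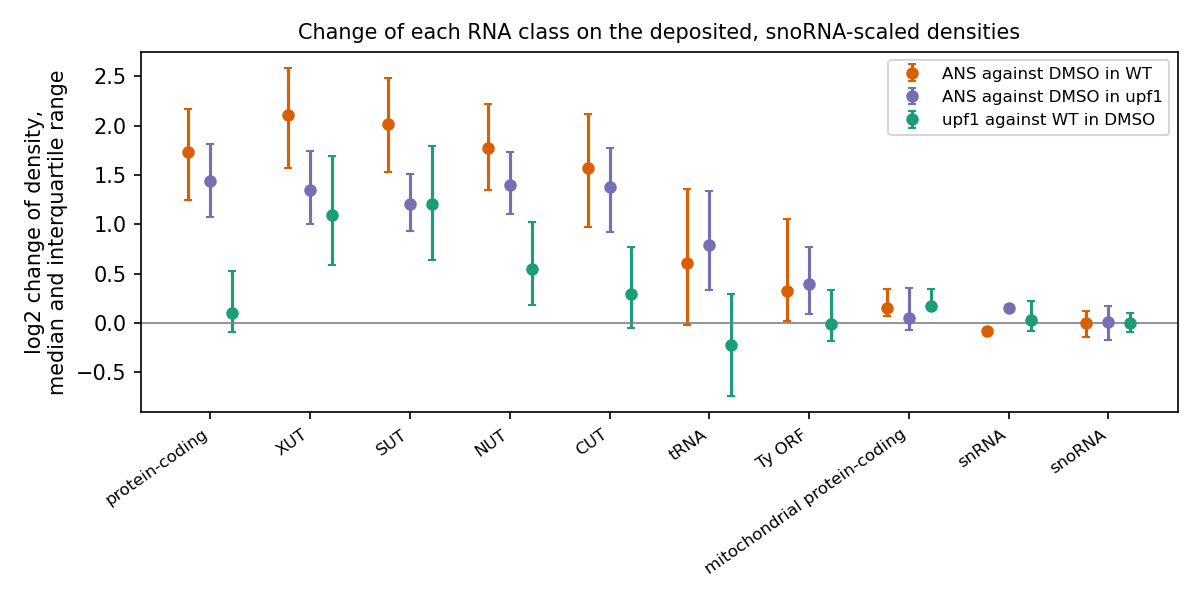
Median log2 change of density for 10 classes of RNA (x axis) on the deposited densities, with interquartile ranges as bars, for ANS in WT, ANS in upf1 and upf1 in DMSO. Long noncoding classes and protein-coding genes lie above 1 under ANS in both strains, while snoRNAs and snRNAs lie near 0, and upf1 in DMSO raises XUTs (median 1.09) and SUTs (median 1.21) above protein-coding genes (median 0.10).

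Among XUTs, 1506 of 1603 rose under ANS in WT and 0 fell by limma (also 0 at an unadjusted p below 0.05), and relative to protein-coding genes 772 rose and 44 fell. XUT1567 had 0 reads in WT DMSO and a density of 0.160 ± 0.0113 (SD, n = 2, 46 reads) in WT ANS. XUT0977 went from 0.0110 ± 2.96e-04 to 0.451 ± 0.0922 (139 reads) and rose by 4.97 ± 0.21 (adjusted p = 3.10e-07). XUT0715, XUT0496 and XUT0429, each with 1 read or none in WT DMSO, reached densities of 0.134 ± 0.0463, 0.0993 ± 0.0399 and 0.132 ± 0.00290. SUT342 rose by 4.28 ± 0.22, SUT671 by 4.15 ± 0.21 and SUT355 by 4.13 ± 0.18, and 760 of 809 SUTs rose. CUT526 rose by 4.87 ± 0.27 and CUT641 by 4.60 ± 0.36. CUT872 had 2 reads in WT DMSO and 32 in WT ANS. As a share of the protein-coding median, the median XUT density was 4.42% ± 0.276 in WT DMSO and 7.49% ± 0.203 in WT ANS (SD, n = 2), a difference of 0.76 on the log2 scale (95% interval 0.58 to 0.95). For SUTs the difference was 0.57 on the log2 scale (95% interval 0.36 to 0.78), for NUTs 0.68 on the log2 scale (95% interval 0.35 to 1.01) and for CUTs 0.15 on the log2 scale (95% interval -0.24 to 0.55), which includes 0. The set test of XUTs gave adjusted p = 0.772 as deposited and adjusted p = 1.03e-06 after rescaling, with adjusted p = 0.154 after rescaling with an estimated correlation. The fitted changes, which hold a pseudocount, had a median above that of all protein-coding genes by 0.38 for XUTs and 0.29 for SUTs. Against the 20 protein-coding genes nearest in density the median difference of the fitted changes was 0.11 for XUTs and 0.08 for SUTs, each above 0 in 6 of 10 bins by density, -0.03 for NUTs and -0.29 for CUTs, the latter below 0 in 9 of 10 bins. It differed with density, from -0.31 for XUTs and -0.36 for SUTs in bin 1 to 0.64 and 0.54 in bin 10. In bins 8 and 9 XUTs had 0.44 and 0.59. The density matched is the mean of all libraries, ANS libraries included. With 5 times the pseudocount the differences from all protein-coding genes reversed to -0.34 for XUTs and -0.27 for SUTs. That pseudocount lies above the median densities of XUTs (0.00651) and SUTs (0.00922) in WT DMSO and pulls their changes toward 0.

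Relative to protein-coding genes, the mRNAs of several abundant housekeeping functions lay lower in WT under ANS. Of all 5777 protein-coding genes 1712 fell on this scale. Abundant mRNAs in general rose less as deposited, with a median of 0.85 in bin 10 by density against 1.73 for all. The lists were not matched on density, so that their medians are not set apart from this trend. List counts are relative to protein-coding genes unless given as deposited, and a set test's direction is against other features. Several lists, such as ribosomal proteins, changed direction in it on rescaling. Of genes of glycolysis and fermentation 16 of 17 fell (16 adjusted over the list alone, median -1.71). Among them were TDH2 (-2.27 ± 0.11), PFK1 (YGR240C, -1.004 ± 0.07) and TDH1 (YJL052W, -0.43 ± 0.14), of which PFK1 and TDH1 had risen on the deposited densities (0.71 ± 0.15 and 1.28 ± 0.20), and PDC5 (YLR134W) lay at 0.19 ± 0.12 (adjusted p = 0.218). Glycolysis had an adjusted p = 1.21e-16 in the set test as deposited (lower, adjusted p = 0.492 with an estimated correlation) and 2.55e-11 after rescaling (lower, 0.233 with an estimated correlation). Of heat shock factor targets 2 of 20 rose and 18 fell (2 and 18 adjusted over the list alone, median -1.67). SSA2 (-2.47 ± 0.09) and SSA1 (-2.42 ± 0.10) fell, FES1 (YBR101C) fell by this scale (-0.27 ± 0.07) and rose as deposited (1.44 ± 0.15), while SSA3 (YBL075C, 0.84 ± 0.08) and SSA4 (YER103W, 0.49 ± 0.12) rose on both. Heat shock factor targets had an adjusted p = 2.33e-16 in the set test as deposited (lower, adjusted p = 0.492 with an estimated correlation) and 2.05e-11 after rescaling (lower, 0.138 with an estimated correlation). Of cytosolic ribosomal protein genes 4 of 138 rose and 128 fell (6 and 129 adjusted over the list alone, median -0.90). Ribosomal proteins had an adjusted p = 0.669 in the set test as deposited (higher, adjusted p = 0.985 with an estimated correlation) and 2.71e-36 after rescaling (lower, 0.142 with an estimated correlation).

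Among proteasome genes, 30 of 33 fell (31 adjusted over the list alone, median -0.70), and among translation factors 1 of 35 rose and 25 fell (2 and 25 adjusted over the list alone, median -0.73). The proteasome had an adjusted p = 0.959 in the set test as deposited (lower, adjusted p = 0.985 with an estimated correlation) and 2.13e-15 after rescaling (lower, 0.138 with an estimated correlation). Translation factors had an adjusted p = 0.266 in the set test as deposited (lower, adjusted p = 0.985 with an estimated correlation) and 6.86e-12 after rescaling (lower, 0.0289 with an estimated correlation). In ergosterol synthesis 1 of 23 rose and 17 fell (1 and 18 adjusted over the list alone, median -0.58), and in respiration and the TCA cycle 3 of 37 rose and 27 fell (3 and 28 adjusted over the list alone, median -0.60). Ergosterol synthesis had an adjusted p = 0.669 in the set test as deposited (higher, adjusted p = 0.985 with an estimated correlation) and 8.13e-10 after rescaling (lower, 0.0483 with an estimated correlation). Respiration had an adjusted p = 0.959 in the set test as deposited (higher, adjusted p = 0.985 with an estimated correlation) and 7.97e-11 after rescaling (lower, 0.142 with an estimated correlation). Of ribosome biogenesis genes 2 of 44 rose and 24 fell (3 and 25 adjusted over the list alone, median -0.29), and of G1 and S phase genes 4 of 20 rose and 11 fell (4 and 11 adjusted over the list alone, median -0.32). Ribosome biogenesis had an adjusted p = 0.141 in the set test as deposited (higher, adjusted p = 0.985 with an estimated correlation) and 2.46e-06 after rescaling (lower, 0.364 with an estimated correlation). G1 and S phase genes had an adjusted p = 0.581 in the set test as deposited (higher, adjusted p = 0.985 with an estimated correlation) and 0.00608 after rescaling (lower, 0.138 with an estimated correlation). The mitochondrially encoded genes stayed near snoRNAs, and relative to nuclear protein-coding genes 8 of 8 fell (8 adjusted over the list alone). ATP6 lay at 0.73 ± 0.23 and COX3 at 0.30 ± 0.15 as deposited, and at -0.97 ± 0.17 and -1.41 ± 0.10 after rescaling. VAR1 fell on both scales (-0.71 ± 0.29, adjusted p = 0.0360). Mitochondrially encoded genes had an adjusted p = 1.70e-09 in the set test as deposited (lower, adjusted p = 0.492 with an estimated correlation) and 1.13e-06 after rescaling (lower, 0.138 with an estimated correlation). Of hexose transporters 2 of 14 rose and 8 fell (3 and 8 adjusted over the list alone, median -0.73). RGT2 (YDL138W, 2.46 ± 0.19) and HXT8 (YJL214W, 2.08 ± 0.25) rose. Hexose transporters had an adjusted p = 7.14e-08 in the set test as deposited (lower, adjusted p = 0.492 with an estimated correlation) and 0.0178 after rescaling (lower, 0.324 with an estimated correlation).

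Other lists had medians above 0 relative to protein-coding genes under ANS in WT, although none in this paragraph passed the set test with an estimated correlation. Of 26 mRNAs known as NMD substrates 16 of 26 rose and 3 fell (17 and 3 adjusted over the list alone, median 0.46). UGA3 (YDL170W), a regulator of GABA use, rose by 3.16 ± 0.17 as deposited and 1.48 ± 0.08 after rescaling, and the telomere genes EST2 (YLR318W) and STN1 (YDR082W) rose by 3.13 ± 0.19 and 2.89 ± 0.16 as deposited. NMD substrates had an adjusted p = 0.00126 in the set test as deposited (higher, adjusted p = 0.947 with an estimated correlation) and 0.0104 after rescaling (higher, 0.142 with an estimated correlation). In the iron regulon 15 of 22 rose and 1 fell (15 and 1 adjusted over the list alone, median 0.52), with ISU1 (YPL135W, 3.39 ± 0.16), VHT1 (YGR065C, 3.39 ± 0.16) and FRE3 (YOR381W, 3.01 ± 0.17) foremost on the deposited densities. The iron regulon had an adjusted p = 0.0134 in the set test as deposited (higher, adjusted p = 0.947 with an estimated correlation) and 0.00931 after rescaling (higher, 0.346 with an estimated correlation). In the phosphate regulon 8 of 15 rose and 1 fell (8 and 2 adjusted over the list alone, median 0.49), with SPL2 (YHR136C, 3.37 ± 0.14), PHO5 (YBR093C, 2.66 ± 0.14) and PHO84 (YML123C, 2.26 ± 0.13). The phosphate regulon had an adjusted p = 0.00335 in the set test as deposited (higher, adjusted p = 0.947 with an estimated correlation) and 0.219 after rescaling (higher, 0.585 with an estimated correlation). Of a-cell genes 6 of 7 rose (6 adjusted over the list alone, median 0.83), led by the pheromone receptor gene STE2 (YFL026W, 2.87 ± 0.12), BAR1 (YIL015W, 2.74 ± 0.14) and MFA1 (YDR461W, 2.49 ± 0.13). A-cell genes had an adjusted p = 0.00282 in the set test as deposited (higher, adjusted p = 0.492 with an estimated correlation) and 0.00293 after rescaling (higher, 0.142 with an estimated correlation). Of meiosis and sporulation genes 12 of 16 rose (12 adjusted over the list alone, median 1.10). Meiosis genes had an adjusted p = 0.174 in the set test as deposited (higher, adjusted p = 0.947 with an estimated correlation) and 0.00462 after rescaling (higher, 0.138 with an estimated correlation).

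The targets of Gcn4, which make amino acids, split under ANS in WT. ARG3 (YJL088W) rose by 5.08 ± 0.18 and ARG4 (YHR018C) by 4.20 ± 0.14, enzymes of arginine synthesis, but of the 38 list members 16 rose and 16 fell relative to protein-coding genes (16 and 16 adjusted over the list alone). Gcn4 targets had an adjusted p = 0.00761 in the set test as deposited (higher, adjusted p = 0.947 with an estimated correlation) and 0.401 after rescaling (lower, 0.766 with an estimated correlation). Of histone genes 7 of 10 rose and 2 fell (7 and 2 adjusted over the list alone, median 0.47), with HHT2 (YNL031C) at 2.27 ± 0.11 and HTB2 (YBL002W) at 2.21 ± 0.11 as deposited. Histones had an adjusted p = 0.0199 in the set test as deposited (higher, adjusted p = 0.947 with an estimated correlation) and 0.454 after rescaling (higher, 0.766 with an estimated correlation). Of G2, M and early G1 genes 8 of 18 rose and 1 fell (8 and 1 adjusted over the list alone, median 0.29), with DSE1 (YER124C, 2.89 ± 0.16), SCW11 (YGL028C, 2.47 ± 0.14) and CDC20 (YGL116W, 2.46 ± 0.18). G2, M and early G1 genes had an adjusted p = 0.00482 in the set test as deposited (higher, adjusted p = 0.947 with an estimated correlation) and 0.122 after rescaling (higher, 0.258 with an estimated correlation). Of mRNA decay and ribosome rescue factors 9 of 26 rose and 6 fell (10 and 6 adjusted over the list alone, median 0.07), with NMD4 (YLR363C, 2.45 ± 0.16), UPF3 (YGR072W, 2.43 ± 0.17) and EDC1 (YGL222C, 2.42 ± 0.17). Decay factors had an adjusted p = 0.0277 in the set test as deposited (higher, adjusted p = 0.947 with an estimated correlation) and 0.454 after rescaling (lower, 0.630 with an estimated correlation). Of the lists that follow, sulfur assimilation passed the set test after rescaling and the others on neither scale. Of the induced environmental stress response 8 of 35 rose and 11 fell (8 and 11 adjusted over the list alone, median 0.12), with adjusted p = 0.783 as deposited. Of pleiotropic drug resistance genes 6 of 17 rose and 2 fell (6 and 2 adjusted over the list alone, median 0.16), with adjusted p = 0.0906, of nitrogen catabolite genes 9 of 23 rose and 5 fell (9 and 5 adjusted over the list alone, median 0.25), with adjusted p = 0.659, and of alpha-cell genes 2 of 4 rose (2 adjusted over the list alone, median 0.96), with adjusted p = 0.959. Of genes of sulfur assimilation 5 of 23 rose and 8 fell (5 and 8 adjusted over the list alone, median -0.06). The stress list had a relative median of 0.12 but a mean of -0.09, and Gcn4 targets a median of 0.00, a mean of 0.19 and a test direction of lower. Sulfur assimilation had an adjusted p = 0.0875 in the set test as deposited (lower, adjusted p = 0.947 with an estimated correlation) and 0.0461 after rescaling (lower, 0.350 with an estimated correlation).

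**Figure D2:**
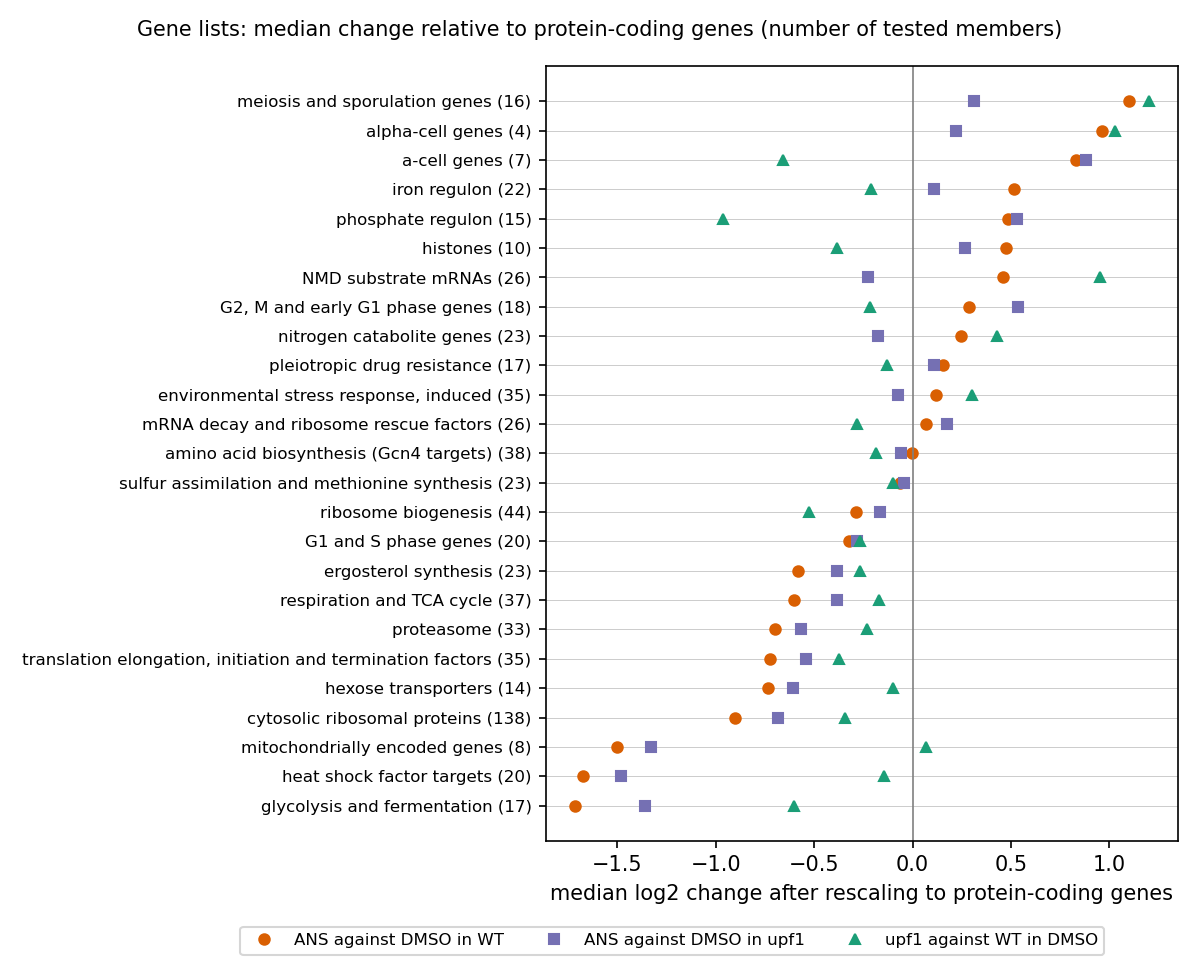
Median log2 change after rescaling to protein-coding genes (x axis) of the members of 25 gene lists (y axis, number of tested members in brackets) for ANS in WT, ANS in upf1 and upf1 in DMSO. Glycolysis lies lowest for ANS in WT (-1.71), and the phosphate regulon lies at -0.96 for upf1 in DMSO and above 0 for ANS in both strains.

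The comparison of upf1 with WT in DMSO asks which RNAs differ without NMD. Apart from NAM7 itself (-4.998 ± 0.19, adjusted p = 2.42e-06), the largest changes among abundant genes were rises of DAL7 (YIR031C), a malate synthase of allantoin breakdown, by 3.58 ± 0.18 (SE, adjusted p = 8.88e-06) and of the sporulation gene ISC10 (YER180C) by 3.19 ± 0.17. DFP1 (YAR023C, 3.17 ± 0.14), SLO1 (YER180C-A, 3.04 ± 0.20), the Mediator subunit gene NUT2 (YPR168W, 2.85 ± 0.19) and YLR125W (2.77 ± 0.17) also rose. The abundant genes that fell included members of the phosphate regulon, whose set test is given below. Among these were the phosphate transporter gene PHO89 (YBR296C, -2.73 ± 0.25, adjusted p = 3.72e-05), SPL2 (-1.68 ± 0.14) and the acid phosphatase gene PHO12 (YHR215W, -1.51 ± 0.16), a near copy of PHO11. The iron transport gene FET3 (YMR058W, -1.08 ± 0.18) and the a-factor gene MFA1 (-1.01 ± 0.13) fell as well. In all, 3663 features rose and 71 fell, and 3585 rose and 1888 fell relative to protein-coding genes. The 71 falls became 36 without upf1 DMSO replicate 1, 45 without WT DMSO replicate 1, 267 without WT ANS replicate 1 and 271 without WT ANS replicate 2.

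XUTs and SUTs stood out among the classes in upf1 DMSO. Of XUTs 958 of 1603 rose and 3 fell (median 1.09), and of SUTs 533 of 809 rose and 4 fell (median 1.21). NUTs rose in 509 of 1448 cases (median 0.55), CUTs in 164 of 898 (median 0.30) and protein-coding genes in 1340 of 5777 (median 0.10). XUT0376 rose by 3.57 ± 0.22 (577 reads in upf1 DMSO) and XUT1467 by 3.49 ± 0.24 (425 reads). XUT1468, XUT0788 and XUT0496, with 1 read or none in WT DMSO, had densities of 0.0955 ± 0.0404, 0.0467 ± 0.00241 and 0.0405 ± 2.62e-04 (SD, n = 2) in upf1 DMSO. XUT0119 fell by 1.08 ± 0.26 (adjusted p = 0.0104). SUT131 (3.55 ± 0.24), SUT262 (3.17 ± 0.20) and SUT745 (3.16 ± 0.24) rose. CUT540, CUT388 and CUT185, with 2 reads or fewer in WT DMSO, had 0.0568 ± 0.00968, 0.0504 ± 0.00580 and 0.0482 ± 0.0202 in upf1 DMSO. The median XUT density rose to 9.69% ± 0.338 of the protein-coding median (SD, n = 2), a difference from WT DMSO of 1.13 on the log2 scale (95% interval 0.95 to 1.32), and that of SUTs from 6.26% ± 0.379 to 14.8% ± 0.741. CUTs went from 4.94% ± 0.783 to 5.55% ± 0.508, with an interval that includes 0 (-0.22 to 0.57). The set test gave adjusted p = 7.88e-14 for XUTs and 7.48e-16 for SUTs, and adjusted p = 0.309 and 0.343 with an estimated correlation. Against the nearest protein-coding genes in density the median difference was 0.52 for XUTs and 0.65 for SUTs, above 0 in 10 of 10 bins by density, 0.10 for NUTs and -0.17 for CUTs.

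**Figure D3:**
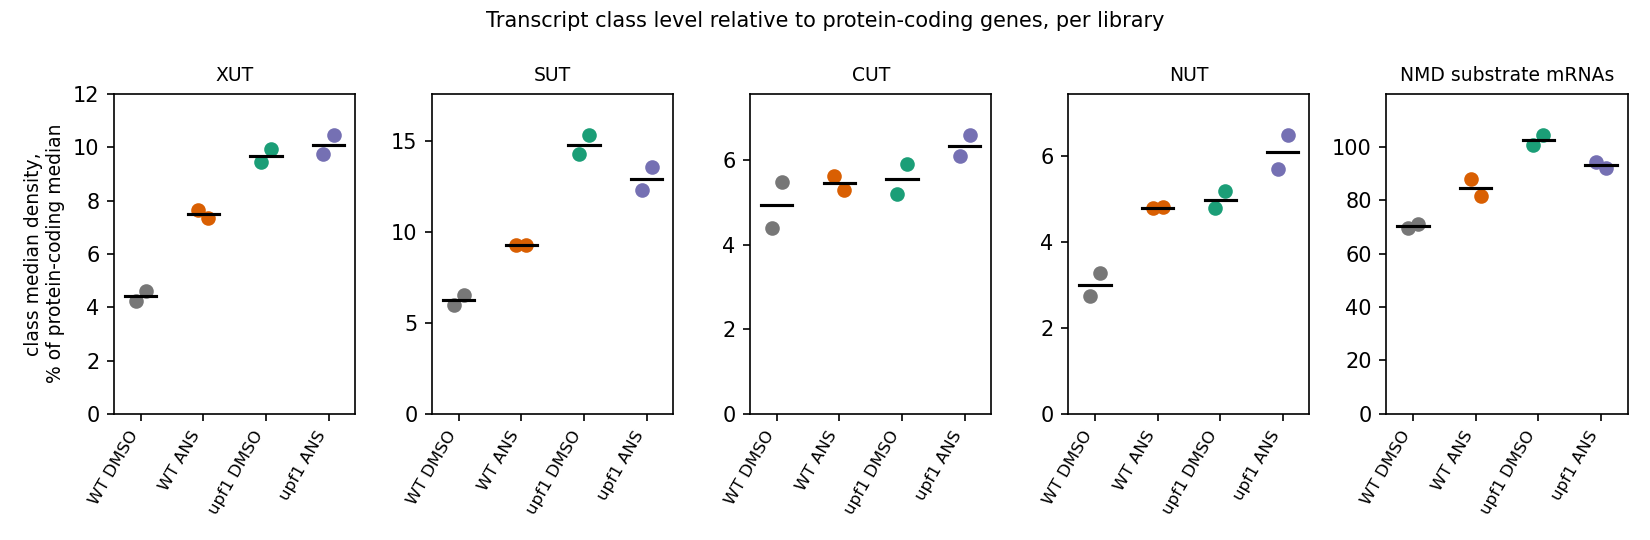
Median density of each class as a percent of the median density of protein-coding genes (y axis, from 0) for each library (points) and group (x axis), with lines at the group means (n = 2). XUTs stand at 4.42% ± 0.276 in WT DMSO, 7.49% ± 0.203 in WT ANS, 9.69% ± 0.338 in upf1 DMSO and 10.1% ± 0.506 in upf1 ANS (SD).

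NMD substrate mRNAs rose in upf1 DMSO, where 19 of 26 rose as deposited (20 adjusted over the list alone, median 1.18). STN1 (2.63 ± 0.16), the iron reductase gene FRE2 (YKL220C, 2.61 ± 0.20) and TEN1 (YLR010C, 2.24 ± 0.16) rose most clearly, CPA1 (YOR303W) rose by 1.82 ± 0.18, EBS1 (YDR206W) by 1.22 ± 0.17 and ALR1 (YOL130W) by 1.05 ± 0.17. NMD substrates in upf1 DMSO had an adjusted p = 1.21e-05 in the set test as deposited (higher, adjusted p = 0.774 with an estimated correlation) and 5.12e-05 after rescaling (higher, 0.0612 with an estimated correlation). Of decay and rescue factors, NMD4 rose by 2.09 ± 0.16, while NMD2 (0.40 ± 0.18, adjusted p = 0.131) and UPF3 (0.07 ± 0.17, adjusted p = 0.816) passed no threshold. Decay factors in upf1 DMSO had an adjusted p = 0.00109 in the set test as deposited (lower, adjusted p = 0.775 with an estimated correlation) and 2.26e-05 after rescaling (lower, 0.0612 with an estimated correlation). The decay list holds NAM7 itself, at 2.39% of its WT density in upf1 DMSO, which moves this test toward lower. The test was not run without NAM7, so it does not show a fall of the other decay factors. In the phosphate regulon 11 of 15 fell as deposited (12 adjusted over the list alone, median -0.72). Phosphate genes in upf1 DMSO had an adjusted p = 3.45e-16 in the set test as deposited (lower, adjusted p = 0.681 with an estimated correlation) and 1.96e-11 after rescaling (lower, 0.0612 with an estimated correlation). Of a-cell genes 4 of 7 fell as deposited (5 adjusted over the list alone, median -0.41), with ASG7 (YJL170C, -1.67 ± 0.21), MFA1 and BAR1 (-0.57 ± 0.14) among them. A-cell genes in upf1 DMSO had an adjusted p = 4.16e-06 in the set test as deposited (lower, adjusted p = 0.681 with an estimated correlation) and 4.46e-05 after rescaling (lower, 0.0612 with an estimated correlation). Of meiosis and sporulation genes 8 of 16 rose as deposited (9 adjusted over the list alone, median 1.14), led by IME2 (YJL106W, 2.69 ± 0.18), SPS4 (YOR313C, 2.21 ± 0.17) and RED1 (YLR263W, 2.18 ± 0.21). Meiosis genes in upf1 DMSO had an adjusted p = 0.0276 in the set test as deposited (higher, adjusted p = 0.774 with an estimated correlation) and 0.0116 after rescaling (higher, 0.126 with an estimated correlation).

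In upf1 DMSO several lists of translation and metabolism lay below protein-coding genes after rescaling. Of all 5777 protein-coding genes 1719 fell on this scale. The median change of protein-coding genes as deposited was 0.55 in bin 1 and -0.09 in bin 10 by rising density, and the lists were not matched on density. Of ribosome biogenesis genes 42 of 44 fell (42 adjusted over the list alone, median -0.53), among them GAR1 (YHR089C, -0.71 ± 0.20 as deposited) and CBF5 (YLR175W, -0.69 ± 0.23). Ribosome biogenesis in upf1 DMSO had an adjusted p = 8.41e-15 in the set test as deposited (lower, adjusted p = 0.774 with an estimated correlation) and 2.09e-15 after rescaling (lower, 0.194 with an estimated correlation). Of ribosomal protein genes 2 of 138 rose and 105 fell (3 and 116 adjusted over the list alone, median -0.34), whereas RPL22B (YFL034C-A) rose by 1.58 ± 0.12 on the deposited densities. Ribosomal proteins in upf1 DMSO had an adjusted p = 1.10e-14 in the set test as deposited (lower, adjusted p = 0.774 with an estimated correlation) and 3.00e-20 after rescaling (lower, 0.255 with an estimated correlation). Of translation factors 1 of 35 rose and 29 fell (1 and 30 adjusted over the list alone, median -0.38), and HEF3 (YNL014W), a paralog of the elongation factor 3 gene, rose by 2.06 ± 0.19. Translation factors in upf1 DMSO had an adjusted p = 4.17e-07 in the set test as deposited (lower, adjusted p = 0.774 with an estimated correlation) and 3.23e-10 after rescaling (lower, 0.0401 with an estimated correlation). Of glycolytic genes 15 of 17 fell (16 fell and 1 rose adjusted over the list alone, median -0.60), with TDH1 at -0.60 ± 0.20 and TDH2 at -0.47 ± 0.16 as deposited. Glycolysis in upf1 DMSO had an adjusted p = 1.84e-08 in the set test as deposited (lower, adjusted p = 0.774 with an estimated correlation) and 6.70e-07 after rescaling (lower, 0.353 with an estimated correlation). The set test also placed lower, as deposited, the proteasome (adjusted p = 7.20e-04, 0.775 with an estimated correlation), histones (0.00501, 0.774) and G1 and S phase genes (0.0124, 0.775). The same held for G2, M and early G1 genes (0.0356, 0.775) and ergosterol synthesis (0.00296, 0.775).

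ANS in upf1 cells asks how RNAs respond to the drug without NMD. As in WT, CIT2 (6.34 ± 0.22, SE, adjusted p = 1.89e-07), NRG1 (5.74 ± 0.16) and SPO24 (5.27 ± 0.19) were among the largest rises, with BOP2 (YLR267W, 5.63 ± 0.27). The chaperone genes SSA1 (-0.88 ± 0.17), HSP82 (YPL240C, -0.78 ± 0.23) and SSA2 (-0.75 ± 0.15) fell, as did the snoRNA SNR54 (-1.12 ± 0.20, adjusted p = 4.60e-04). In all, 10273 features rose and 31 fell, and 1980 rose and 2187 fell relative to protein-coding genes, whose median rise was 1.44. XUTs rose by a median of 1.35 and SUTs by 1.21, in fitted values that hold the pseudocount. Relative to the protein-coding median, the XUT level went from 9.69% ± 0.338 in upf1 DMSO to 10.1% ± 0.506 in upf1 ANS, a difference of 0.06 on the log2 scale (95% interval -0.13 to 0.24), and the SUT level differed by -0.19 on the log2 scale (95% interval -0.41 to 0.02). The set test gave adjusted p = 0.00143 for XUTs (lower than other features, adjusted p = 0.473 with an estimated correlation) and after rescaling adjusted p = 0.549 (higher). Against the nearest protein-coding genes in density the difference was -0.18 for XUTs and -0.31 for SUTs. The 31 falls became 20 without upf1 DMSO replicate 2.

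Chaperone and glycolytic mRNAs also fell relative to protein-coding genes in upf1 under ANS. Of all 5777 protein-coding genes 1575 fell on this scale. Abundant mRNAs rose less in upf1 as well, with a median of 0.83 as deposited in bin 10 against 1.44 for all. Of heat shock factor targets 20 of 20 fell (20 adjusted over the list alone, median -1.48), and of glycolytic genes 15 of 17 fell (15 adjusted over the list alone, median -1.36). Heat shock factor targets in upf1 had an adjusted p = 1.60e-23 in the set test as deposited (lower, adjusted p = 0.412 with an estimated correlation) and 9.96e-14 after rescaling (lower, 0.128 with an estimated correlation). Glycolysis in upf1 had an adjusted p = 3.20e-09 in the set test as deposited (lower, adjusted p = 0.760 with an estimated correlation) and 2.37e-08 after rescaling (lower, 0.328 with an estimated correlation). Of ribosomal protein genes 4 of 138 rose and 125 fell (5 and 125 adjusted over the list alone, median -0.68), though RPS9A (YPL081W) rose by 1.39 ± 0.07 on that scale. Ribosomal proteins in upf1 had an adjusted p = 0.00595 in the set test as deposited (higher, adjusted p = 0.865 with an estimated correlation) and 1.51e-26 after rescaling (lower, 0.246 with an estimated correlation). In the phosphate regulon 8 of 15 rose (8 rose and 1 fell adjusted over the list alone, median 0.53), with SPL2 at 4.19 ± 0.14, PHO89 at 3.995 ± 0.25 and PHO84 at 2.43 ± 0.13 as deposited. The phosphate regulon in upf1 had an adjusted p = 2.35e-05 in the set test as deposited (higher, adjusted p = 0.760 with an estimated correlation) and 4.95e-05 after rescaling (higher, 0.188 with an estimated correlation). Of a-cell genes 7 of 7 rose (7 adjusted over the list alone, median 0.88), and of G2, M and early G1 genes 14 of 18 rose (14 adjusted over the list alone, median 0.54). A-cell genes in upf1 had an adjusted p = 4.29e-05 in the set test as deposited (higher, adjusted p = 0.412 with an estimated correlation) and 5.80e-06 after rescaling (higher, 0.0878 with an estimated correlation). G2, M and early G1 genes in upf1 had an adjusted p = 2.35e-05 in the set test as deposited (higher, adjusted p = 0.760 with an estimated correlation) and 4.23e-06 after rescaling (higher, 0.0766 with an estimated correlation). ARG4 (3.85 ± 0.14), ARG3 (3.85 ± 0.18), ISU1 (3.46 ± 0.16) and the cyclin gene PCL1 (YNL289W, 3.14 ± 0.17) rose. Of NMD substrates 6 of 26 rose and 12 fell (6 and 12 adjusted over the list alone, median -0.23). NMD substrates in upf1 had an adjusted p = 0.0509 in the set test as deposited (higher, adjusted p = 0.865 with an estimated correlation) and 0.202 after rescaling (lower, 0.435 with an estimated correlation). Mitochondrially encoded genes in upf1 had an adjusted p = 1.01e-10 in the set test as deposited (lower, adjusted p = 0.412 with an estimated correlation) and 5.10e-06 after rescaling (lower, 0.162 with an estimated correlation). Hexose transporters in upf1 had an adjusted p = 0.00310 in the set test as deposited (lower, adjusted p = 0.760 with an estimated correlation) and 0.0733 after rescaling (lower, 0.435 with an estimated correlation).

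Under ANS the mutant and WT differed in fewer RNAs. COS12 (YGL263W) was higher in upf1 by 2.86 ± 0.23 (SE, adjusted p = 9.91e-04), DFP1 by 1.72 ± 0.14, XUT0376 by 1.63 ± 0.22 and SUT354 by 1.62 ± 0.23. NAM7 (-5.76 ± 0.19), PHO89 (-2.31 ± 0.25), PHO5 (-1.17 ± 0.14) and MFA1 (-1.15 ± 0.13) were lower. Of XUTs 91 of 1603 were higher and 0 lower by limma (15 at an unadjusted p below 0.05), and of SUTs 60 of 809 were higher. Adjusted over the class alone, 193 XUTs were higher and 2 lower, and 181 SUTs were higher. Relative to protein-coding genes 132 XUTs and 112 SUTs were higher. Relative to protein-coding genes the XUT level was higher by 0.43 on the log2 scale (95% interval 0.25 to 0.61) and the SUT level by 0.48 on the log2 scale (95% interval 0.26 to 0.69). The set test gave adjusted p = 1.60e-09 for XUTs and 1.47e-11 for SUTs, and adjusted p = 0.643 for both with an estimated correlation. Against the nearest protein-coding genes in density the difference was 0.18 for XUTs and 0.24 for SUTs. Over all features 312 were higher and 25 lower, and 629 and 219 relative to protein-coding genes. These counts moved when libraries were left out, also those of upf1 DMSO, which are not part of this comparison. The XUT level difference ranged from 0.378 to 0.48 with each library left out. The features higher numbered 8 without upf1 ANS replicate 1, 10 without upf1 ANS replicate 2, 107 and 112 without upf1 DMSO replicates 1 and 2, and 99 and 1001 without WT ANS replicates 1 and 2. Those lower numbered 8 and 5 without upf1 ANS replicates 1 and 2, 13 and 15 without upf1 DMSO replicates 1 and 2, and 58 without WT ANS replicate 1.

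The phosphate regulon remained lower in upf1 under ANS, where 9 of 15 fell as deposited (14 adjusted over the list alone, median -0.66). Phosphate genes in upf1 against WT under ANS had an adjusted p = 8.77e-22 in the set test as deposited (lower, adjusted p = 0.301 with an estimated correlation) and 1.60e-20 after rescaling (lower, 0.0530 with an estimated correlation). Of a-cell genes 3 of 7 fell as deposited (5 adjusted over the list alone, median -0.54), including AGA2 (YGL032C, -0.92 ± 0.13). A-cell genes in upf1 against WT under ANS had an adjusted p = 1.04e-07 in the set test as deposited (lower, adjusted p = 0.301 with an estimated correlation) and 1.63e-07 after rescaling (lower, 0.0719 with an estimated correlation). Of the induced environmental stress genes 3 of 35 rose as deposited (14 adjusted over the list alone, median 0.52), with YGP1 (YNL160W, 0.98 ± 0.16), CYC7 (YEL039C, 1.17 ± 0.25) and HXK1 (0.82 ± 0.18) higher in the mutant. Stress genes had an adjusted p = 2.20e-06 in the set test as deposited (higher, adjusted p = 0.895 with an estimated correlation) and 2.64e-08 after rescaling (higher, 0.230 with an estimated correlation). The iron genes SIT1 (YEL065W, -0.89 ± 0.16) and FET3 (-0.97 ± 0.18) were lower, and of the iron regulon 2 of 22 fell as deposited (4 fell and 1 rose adjusted over the list alone, median -0.10). The iron regulon in upf1 against WT under ANS had an adjusted p = 6.23e-04 in the set test as deposited (lower, adjusted p = 0.895 with an estimated correlation) and 0.00336 after rescaling (lower, 0.323 with an estimated correlation). Of ribosome biogenesis genes 18 of 44 fell (35 adjusted over the list alone, median -0.39). Ribosome biogenesis in upf1 against WT under ANS had an adjusted p = 6.98e-20 in the set test as deposited (lower, adjusted p = 0.762 with an estimated correlation) and 5.68e-23 after rescaling (lower, 0.173 with an estimated correlation). HTB1 (YDR224C) lay at -0.49 ± 0.11 relative to protein-coding genes, and of histone genes 4 of 10 fell (8 adjusted over the list alone, median -0.37). Histones in upf1 against WT under ANS had an adjusted p = 6.08e-09 in the set test as deposited (lower, adjusted p = 0.301 with an estimated correlation) and 2.75e-07 after rescaling (lower, 0.216 with an estimated correlation). Of NMD substrates 2 of 26 rose as deposited (9 adjusted over the list alone, median 0.22), with TEN1 (0.91 ± 0.16) and CPA1 (0.81 ± 0.18) higher in the mutant. NMD substrates in upf1 against WT under ANS had an adjusted p = 0.0203 in the set test as deposited (higher, adjusted p = 0.895 with an estimated correlation) and 0.00469 after rescaling (higher, 0.173 with an estimated correlation). Of translation factors 1 of 35 rose and 4 fell (1 and 7 adjusted over the list alone, median -0.19). Translation factors in upf1 against WT under ANS had an adjusted p = 6.16e-07 in the set test as deposited (lower, adjusted p = 0.895 with an estimated correlation) and 1.88e-09 after rescaling (lower, 0.0469 with an estimated correlation).

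The interaction asks whether ANS acted differently without Upf1. Its largest values were falls, which mean a smaller ANS effect in upf1. SRL3 (YKR091W) had -2.53 ± 0.28 (SE, adjusted p = 0.00615), with densities of 0.0418 ± 0.00708 in WT DMSO, 1.02 ± 0.261 in WT ANS, 0.207 ± 0.0149 in upf1 DMSO and 0.818 ± 0.0535 in upf1 ANS (SD, n = 2). XUT0988 had -2.78 ± 0.29 and YMR158C-A -2.47 ± 0.63, and YPL152W-A, with 2 reads in WT DMSO, had densities of 0.00696 ± 0.00985, 0.142 ± 0.0193, 0.191 ± 0.00402 and 0.392 ± 0.0691 in the same order. The 2 features of the rule with a larger effect in upf1 were the valine tRNA tV(CAC)H (1.26 ± 0.32, adjusted p = 0.0408) and SPL2 (0.81 ± 0.20, adjusted p = 0.0334). Of XUTs 251 of 1603 had a smaller ANS effect in upf1 and 3 a larger one (median -0.72). Adjusted over the class alone, these counts were 371 and 3 for XUTs and 284 and 5 for SUTs. Of SUTs the counts over all features were 188 and 5 of 809 (median -0.75), and of protein-coding genes 372 and 3 of 5777 (median -0.15). Relative to protein-coding genes the ANS effect on the XUT level differed between strains by -0.70 on the log2 scale (95% interval -0.96 to -0.44) and that on the SUT level by -0.76 on the log2 scale (95% interval -1.06 to -0.46). For CUTs it differed by 0.04 on the log2 scale (95% interval -0.51 to 0.60) and for NUTs by -0.39 on the log2 scale (95% interval -0.86 to 0.08), both of which include 0. The set test gave adjusted p = 9.11e-07 for XUTs and 1.99e-10 for SUTs, and adjusted p = 0.463 for both with an estimated correlation. Against the nearest protein-coding genes in density the median fitted interaction was -0.37 for XUTs and -0.42 for SUTs, below 0 in 10 of 10 bins, -0.02 for NUTs and 0.13 for CUTs. With 5 times the pseudocount, which lies above the median XUT density in WT DMSO (0.00651), the XUT difference from all protein-coding genes shrank to -0.12.

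Of NMD substrates 9 of 26 fell as deposited (16 adjusted over the list alone, median -0.74) in the interaction. STN1 (-1.92 ± 0.23), FRE2 (-1.82 ± 0.28), TEN1 (-1.33 ± 0.23), CPA1 (-1.01 ± 0.25) and EBS1 (-0.93 ± 0.23) passed the threshold. NMD substrates in the interaction had an adjusted p = 2.32e-06 in the set test as deposited (lower, adjusted p = 0.800 with an estimated correlation) and 2.25e-06 after rescaling (lower, 0.0771 with an estimated correlation). The level of NMD substrates relative to all protein-coding genes was 70.3% ± 1.01 in WT DMSO, 84.6% ± 4.51 in WT ANS, 102% ± 2.66 in upf1 DMSO and 93.3% ± 1.48 in upf1 ANS (SD, n = 2). ALD3 (YMR169C, -1.91 ± 0.26), RTN2 (YDL204W, -1.49 ± 0.28), HEF3 (-1.29 ± 0.27) and RPL22B (-1.06 ± 0.17) also had a smaller ANS effect in upf1. Over all features 22 had a larger and 968 a smaller ANS effect in upf1, and 84 and 1216 after rescaling. The count of smaller effects was 0 without upf1 ANS replicate 2 by limma (1704 at an unadjusted p below 0.05), 265 without upf1 ANS replicate 1, and 13 and 335 without upf1 DMSO replicates 1 and 2. It was 1704 and 543 without WT ANS replicates 1 and 2, and 554 without WT DMSO replicate 1. That of larger effects was 0 without upf1 ANS replicate 2 (80 at an unadjusted p below 0.05), 7 without upf1 ANS replicate 1, 2 without upf1 DMSO replicate 1, 11 without WT DMSO replicate 1, and 52 and 56 without WT ANS replicates 1 and 2.

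The effects of ANS in WT and of the upf1 mutation in DMSO were compared feature by feature. Of XUTs 945 rose in both (900 for independent lists), and 640 rose in both relative to protein-coding genes (448 for independent lists). Over all features 3627 rose in both (3302 for independent lists) and 3 fell in both (0.245). After rescaling, 2386 rose in both (1260) and 1050 fell in both (369). Both effects share the WT DMSO libraries. In 50 simulations of unchanged groups against those libraries the mean number of features that rose in both was 0.02. Unchanged groups give hardly any calls, so that this mean cannot gauge the overlap where 10439 of 11579 features rose under ANS in WT. The correlation of the changes across features, which are not independent replicates, was 0.52, against a mean of 0.51 in the simulations. Unchanged groups that share their controls give about that simulated value by design, so its nearness to 0.52 does not show whether the effects are alike. The covariance was 0.344, against a mean of 0.0448. With each effect taken against a different WT DMSO library, the correlation was 0.40 and 0.40 for the 2 ways round, and 0.31 and 0.33 over XUTs. Then 2760 and 3093 features rose in both (2447 and 2769 for independent lists).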

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

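The tests of explanations here, the measure of class level and the match on density were chosen after the results were seen, while the interaction tests of features and lists were planned. Each of the results below is a difference of the ANS effect between upf1 and WT, negative where ANS raised the RNA less in upf1.

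The level of XUTs relative to protein-coding genes differed by -0.704, that of SUTs by -0.764, that of other open reading frames by -0.311 and that of NMD substrate mRNAs by -0.401. These levels hold no pseudocount. In the fitted values, which do, the median interaction was -0.204 for other open reading frames and -0.152 for protein-coding genes. Against protein-coding genes of the same density it was 0.045 for other open reading frames and -0.613 for NMD substrates. The levels of XUTs and SUTs rose under ANS in WT. In the fitted values the differences were 0.378 and 0.286 against all protein-coding genes. They reversed with 5 times the pseudocount (-0.338 and -0.268), which lies above the median XUT and SUT densities in WT DMSO (0.00651 and 0.00922). So large a pseudocount pulls the changes of sparse features toward 0. With the pseudocount as set, the differences against protein-coding genes of the same density were 0.109 and 0.076, from -0.309 and -0.362 in the bin of lowest density to 0.640 and 0.536 in the highest. After rescaling the set tests gave adjusted p = 0.154 and 0.194 with an estimated correlation. Low density as a source of part of the XUT interaction stays open, since the fitted value was -0.564 against all protein-coding genes and -0.365 against those of the same density. The latter lay below 0 in 10 of 10 bins by density, but by 0.2 or more in 7. It was -0.059 and -0.052 in bins 1 and 2, of lowest density, and -0.994 in bin 10, of highest density. Low density alone would set the largest difference in the sparsest bins, so these values argue against it as the whole source. A fixed share of sense reads counted on the opposite strand is argued against as the whole source of XUT reads. It would leave the XUT level alike in both strains, and upf1 raised that level by 1.133 in DMSO. A share that adds to the XUT reads in every library is not excluded by this value. An ANS effect on RNAs that Upf1 lowers also stays open, as a hypothesis. Over XUTs and SUTs, each against genes of the same density, the ANS change in WT had a rank correlation of 0.327 or more with the upf1 change in 4 splits of the DMSO libraries, and the ANS change in upf1 one of -0.163 to -0.094. The density matched is the mean of all libraries. For XUTs, ANS in WT and upf1 in DMSO went from -0.309 and 0.375 in bin 1 to 0.640 and 1.559 in bin 10 by that density. The correlation in WT is not set apart from this trend. XUTs may have been spared Upf1-dependent decay while ribosomes stalled.

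Protein-coding genes rose over snoRNAs under ANS in both strains. Loss of short RNAs from the ANS libraries is argued against as the whole source, since long mitochondrially encoded RNAs rose by a median of only 0.148 (quartiles 0.076 to 0.345). An even background of reads is argued against, because bin 6 of 10 bins of protein-coding genes by density rose by 1.831 and bin 1 by 1.838, over a 15.421-fold difference of density. A change of mRNA per cell, or of snoRNAs and mitochondrial RNAs alike, may be the source, and no biological explanation was tested.

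The phosphate regulon had a median interaction of 0.273 relative to protein-coding genes (adjusted p = 7.36e-04 by the set test after rescaling, adjusted p = 0.253 with an estimated correlation). Protein-coding genes had a median of 0.058 on that scale. Of phosphate genes 11 of 15 and of a-cell genes 4 of 7 were lower in upf1 in DMSO, and 9 and 3 under ANS (adjusted p = 0.681 and 0.301 with an estimated correlation for each list). Alpha cells among the upf1 cultures are argued against, since MF(ALPHA)1 reached 0.367% of the density of MFA1, and STE2 and MFA2 did not fall. The lower of the log2 changes of STE2 and MFA2 in DMSO was 0.057, and the larger of their SEs was 0.137. The scaling on snoRNAs is argued against by a median of -0.965 for the phosphate genes in DMSO after rescaling. Growth of the upf1 cultures apart from the WT cultures, which could set phosphate genes lower in both conditions, stays open, with -0.659 under ANS.

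Among gene lists, the median interaction relative to protein-coding genes was -0.545 for NMD substrates (adjusted p = 2.25e-06 by the set test after rescaling). It was 0.208 for ribosomal proteins (1.01e-14), 0.361 for glycolysis (3.79e-06), 0.172 for hexose transporters (0.0293) and 0.18 for translation factors (1.28e-05). The stress response had 0.195 (0.0221), the proteasome 0.19 (3.68e-06) and G2, M and early G1 genes 0.216 (4.80e-04). Respiration had 0.182 (1.28e-05) and ergosterol synthesis 0.188 (3.79e-06). With an estimated correlation none of these lists passed, with a smallest adjusted p = 0.0771 after rescaling and adjusted p = 0.800 as deposited. Protein-coding genes themselves had a median interaction of 0.058 after rescaling (quartiles -0.224 to 0.211). Their ANS rise as deposited was 1.99 in WT and 1.56 in upf1 in bin 3 of 10 bins by density, but 0.85 and 0.83 in bin 10. The lists were not matched on density, so that their values are not set apart from this trend.

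Single features differed as follows. The tRNA tV(CAC)H had an interaction of 1.262 and SPL2 of 0.814. XUT0988 had -2.777, SRL3 -2.528 and YMR158C-A -2.471. Among NMD substrates STN1 had -1.921, FRE2 -1.818, TEN1 -1.331, EBS1 -0.926 and CPA1 -1.009. RPL22B had -1.06, HEF3 -1.288, ALD3 -1.907 and RTN2 -1.489.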

How the results depend on the processing

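The alternatives with voom, with 80 or more reads, with protein-coding genes of the same density and with the WT DMSO libraries split were chosen after the results were seen. Over all alternatives, 284 values of named genes in a comparison gave 5632 values, of which 5228 kept direction and side of the threshold, 258 lost the call, 122 gained one, 15 changed sign with a call before or after and 9 changed sign without a call. Apart from those always named, these genes were chosen by the size or adjusted p of their changes in the same data. The share kept therefore does not show how calls in general fared. With the smaller pseudocount 149 of 312 rises for upf1 under ANS were kept, and 10384 of 10439 for ANS in WT. With the larger pseudocount 358 of 968 falls of the interaction were kept, and 311 of 312 rises for upf1 under ANS. Rescaling to snoRNAs, no filter, limma without trend and limma with robust moderation moved no count over all features by more than 1.5 times. Where a library was left out, the lone sample was assumed to vary like the other groups. In the simulated data, in which few features changed, 2 replicates recovered 8.96% of 1.5-fold changes, so that absent calls do not show absent change. Count tests with edgeR and DESeq2 were not run. The causes of the moves below were not tested.

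With a replicate block the counts of higher and lower features were 10492 and 48 for ANS in WT, 10336 and 34 for ANS in upf1, 3560 and 81 for upf1 in DMSO, 277 and 30 for upf1 under ANS, and 22 and 842 for the interaction, and the overlap was 3517 and 4. No count moved by more than 1.5 times.

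With a minimum of 80 reads, 4 features had a higher interaction, and the median of XUTs minus that of protein-coding genes was 0.486 for ANS in WT, 1.207 for upf1 in DMSO and -0.686 for the interaction. With a 2-fold minimum the falls numbered 14 for ANS in WT, 7 for ANS in upf1, 30 for upf1 in DMSO and 13 for upf1 under ANS, and 1 feature fell in both effects compared. With the filter at the 25th percentile, 13 features had a higher interaction. XUTs minus protein-coding genes then gave 0.552 for ANS in WT, -0.03 for ANS in upf1, 1.189 for upf1 in DMSO and -0.692 for the interaction, and the SUT level changed by -0.191 (-0.379 to -0.003) for ANS in upf1. With only the 4 samples compared, 48 features fell for ANS in upf1, 201 for upf1 in DMSO, and 534 were higher and 64 lower for upf1 under ANS.

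On the deposited densities with an estimated correlation the classes past the set test numbered 3 for ANS in WT, 3 for ANS in upf1, and 0 each for upf1 in DMSO, upf1 under ANS and the interaction. XUTs then had adjusted p = 0.473 for ANS in upf1, 0.309 for upf1 in DMSO, 0.643 for upf1 under ANS and 0.463 for the interaction, and SUTs 0.625, 0.343, 0.643 and 0.463. Of lists, 0 passed on the deposited densities in each of the 5 comparisons. After rescaling with an estimated correlation, protein-coding genes passed as lower for ANS in WT (0.0289), upf1 in DMSO (0.00175) and upf1 under ANS (0.00295) and as higher for the interaction (0.00911). Likewise translation factors passed for ANS in WT (0.0289), upf1 in DMSO (0.0401) and upf1 under ANS (0.0469), and ergosterol synthesis for ANS in WT (0.0483).

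Against the 20 protein-coding genes nearest in density XUTs gave 0.109 for ANS in WT, -0.185 for ANS in upf1, 0.523 for upf1 in DMSO, 0.176 for upf1 under ANS and -0.365 for the interaction. Bins by XUT density, tried first, gave 0.141, -0.137, 0.589, 0.196 and -0.401, but their highest bin set 161 XUTs against 4877 protein-coding genes and was no match. With ANS against WT DMSO replicate 1 and upf1 against replicate 2, 1 feature fell in both effects. With 5 times the pseudocount 827 features were higher and 62 lower for upf1 under ANS, and 10 higher and 360 lower for the interaction. XUTs minus protein-coding genes reversed to -0.338 for ANS in WT and gave -0.384 for ANS in upf1, 0.438 for upf1 in DMSO, 0.337 for upf1 under ANS and -0.118 for the interaction. For ANS in WT, SUTs minus protein-coding genes reversed to -0.268 and the XUT set test turned to lower with adjusted p = 0.809. With 0.2 times the pseudocount 149 features were higher and 15 lower for upf1 under ANS. XUTs minus protein-coding genes gave 0.74 for ANS in WT, 0.015, reversed, for ANS in upf1, 1.392 for upf1 in DMSO and -0.885 for the interaction.

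Rescaled to protein-coding genes, the higher and lower features numbered 4069 and 2261 for ANS in WT, 1980 and 2187 for ANS in upf1, 629 and 219 for upf1 under ANS, 84 higher for the interaction and 1888 lower for upf1 in DMSO. The overlap became 2386 and 1050. XUTs minus protein-coding genes gave 0.692 for ANS in WT, 0.044, reversed, for ANS in upf1, 1.207 for upf1 in DMSO and -0.78 for the interaction. For ANS in WT the set test of protein-coding genes reversed to lower (adjusted p = 4.22e-04), and XUTs (1.03e-06) and SUTs (3.19e-05) passed. For ANS in upf1, 5 classes passed, XUTs (0.549) and SUTs (0.120) did not, and NUTs reversed to higher (0.0104), ribosomal proteins to lower (1.51e-26) and ribosome biogenesis to lower (0.0282). For the interaction 17 lists passed. With an estimated correlation after rescaling, NUTs had adjusted p = 0.527 in the set test for ANS in upf1, and no list passed for the interaction. Genes called in the opposite direction for ANS in WT were FES1 (-0.265), TDH1 (-0.427), PFK1 (-1.004), ATP6 (-0.974) and COX3 (-1.407), while NAM7 changed sign and lost its call (-0.041, adjusted p = 0.789). For ANS in upf1 they were FES1 (-0.271), SSA3 (-0.287), PFK1 (-0.751), ATP6 (-0.858), COB (-0.835), EBS1 (-0.272) and ALR1 (-0.306), while SNF3 (-0.218, adjusted p = 0.239) and NAM7 (-0.312, adjusted p = 0.0843) lost their calls.

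With voom, 138 features fell for upf1 in DMSO, 996 were higher and 91 lower for upf1 under ANS, and 1800 were lower for the interaction. XUTs minus protein-coding genes gave 0.748 for ANS in WT, 0.027, reversed, for ANS in upf1, 1.316 for upf1 in DMSO and -0.872 for the interaction.

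With each library left out in turn, the falls ranged from 31 to 103 for ANS in WT, 20 to 44 for ANS in upf1 and 36 to 271 for upf1 in DMSO. For upf1 under ANS 8 to 1001 features were higher and 5 to 58 lower, and for the interaction 0 to 56 were higher and 0 to 1704 lower by limma, where the 0 and 0 stood at 80 and 1704 at an unadjusted p below 0.05. XUTs minus protein-coding genes ranged from 0.305 to 0.419 for ANS in WT, 0.938 to 1.063 for upf1 in DMSO and -0.619 to -0.499 for the interaction, and the XUT set test for ANS in WT from 0.114 to 0.795, turning to lower without WT ANS replicate 1 (0.192) and replicate 2 (0.716). The SUT level for ANS in upf1 ranged from -0.266 to -0.122, and that of NMD substrates from -0.162 to -0.109 for ANS in upf1 and 0.087 to 0.196 for upf1 under ANS, with intervals that included 0 in part. The level interaction ranged from -0.768 to -0.640 for XUTs and -0.836 to -0.692 for SUTs, with intervals that excluded 0 throughout.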

Other observations

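The features described here were chosen after their values were seen, and their values are on the deposited scale. Of the 4 open reading frames of the 2-micron plasmid, a multicopy plasmid of the yeast nucleus, 3 were higher in upf1 in DMSO. R0010W, the plasmid's recombinase gene, had a density of 0.228 ± 0.0548 in WT DMSO, 1.12 ± 0.197 in WT ANS, 1.35 ± 0.101 in upf1 DMSO and 2.56 ± 0.173 in upf1 ANS (SD, n = 2), a log2 change of 2.57 ± 0.19 (SE) for upf1 in DMSO with adjusted p = 1.74e-05 by limma. R0040C, which serves plasmid partition, had 0.869 ± 0.0323, 6.12 ± 0.855, 5.27 ± 0.0469 and 10.6 ± 0.0491 in the same order, a change of 2.60 ± 0.12 with adjusted p = 7.15e-06. R0030W changed by 0.60 ± 0.17 (adjusted p = 0.0197), while R0020C, at 0.40 ± 0.20, did not pass (adjusted p = 0.166).

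Of 12 other noncoding RNAs, 6 rose and 2 fell under ANS in WT (median 0.74), and the set test gave adjusted p = 4.68e-07 as deposited (lower than other features) and 0.0564 after rescaling. TLC1, the telomerase RNA, had a log2 change of 0.05 ± 0.16 (SE, adjusted p = 0.777), NME1, the RNA of the RNase MRP, 0.05 ± 0.10 (adjusted p = 0.630) and RPR1, the RNA of RNase P, -0.38 ± 0.18 (adjusted p = 0.0687). SCR1, the RNA of the signal recognition particle, fell by 1.24 (adjusted p = 0.0200). The regulatory noncoding RNAs SRG1, upstream of SER3, and ICR1, upstream of FLO11, rose by 2.13 ± 0.12 and 1.57 ± 0.24 under ANS, and by 1.06 ± 0.12 and 2.37 ± 0.24 in upf1 in DMSO (adjusted p = 9.71e-05 and 6.15e-05).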
